A study of Drosophila melanogaster with 4 samples.

How the data were processed

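Polyadenylated RNA from whole Drosophila melanogaster larvae at 100 h after egg laying was sequenced in paired-end mode on an Illumina MiSeq, per the labels' protocols. There were 4 libraries, 2 labelled wildtype and 2 labelled as homozygous for a Kr-h1 mutant allele. The submitters' processing notes name TopHat2, Cufflinks and Cuffdiff. Their versions and settings, the genome build and the annotation were not given in the sources used here.

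The data were the authors' deposited Cuffdiff table of gene-level comparisons, with 16198 loci. Its FPKM values (fragments scaled to transcript length and sequencing depth) were made by the authors with Cuffdiff, 1 value per group over its 2 libraries, and the scaling between libraries was not stated. The deposited log2 fold change sets mutant-labelled over wildtype-labelled FPKM without a pseudocount, and it matched the log2 of the 2 deposited values. Cuffdiff's test statistic, a score, is in the deposited table too and was not used further. The deposited p-value and q-value are Cuffdiff's, and the q-value matched a Benjamini-Hochberg adjustment recomputed from the deposited p-values. Per the file's status column, 7058 loci were tested, 9135 were not tested and 5 were set aside for too many fragments. A gene is called higher or lower here where the deposited q-value is at most 0.05.

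The table carries no value per library, so no standard deviation, standard error or replicate-level test could be computed. The depth of the libraries is unknown, because no read counts were given and the low FPKM values did not fall into steps of whole reads. The smallest p-value in the deposited table is 5e-05, which is shared by many genes and gives a smallest q-value of 0.000889. The labels do not say whether the libraries of a group came from separate cultures or collections of larvae. The p-values then measure at most the spread between these libraries, which may be technical. Cuffdiff's settings were not given, so how that spread entered the p-values is unknown.

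Transcript accessions in the table were matched to NCBI gene symbols of Release 6, and 30273 of 30529 accessions matched (99.2%). Loci with several symbols (431 of the tested loci) and loci whose coordinates are shared with another row (3230 of the tested loci, where the position is that of the whole bundle of overlapping transcripts) were kept. Their values are uncertain where fragments could be divided between the genes, as are those of near-identical members of gene families. The strand setting of the counting was not given in the sources used here. Coordinates are those of the deposited table, written with a 1-based start. Of 15397 loci with 1 symbol, 98.7% overlapped the Release 6 position of that gene. The exonic length of each gene was the union of its exons in Ensembl release 115, and 99.8% of tested loci had one. A locus with several symbols took the longest of its genes (3937 nucleotides for the row of Lcp9 and egg). A locus without a length took the median length in matching and correction. GC content was not examined.

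Ratios are log2((mutant-labelled FPKM + 1)/(wildtype-labelled FPKM + 1)), with a pseudocount of 1, which understates the change of genes with low values. Folds are ratios of the 2 FPKM values, and none is given against a value of 0. Before the data were examined, 32 gene lists, the tests and the rule for named genes were fixed. Current symbols for some list members with older names were added by hand after the table had been seen. For the 26 lists with at least 5 tested members, the share of members called higher, and separately lower, was compared with that of all other tested genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 52 tests. The median ratio of each list was placed among 10000 random lists of the same size matched on mean FPKM in 20 bins, as a description. Genes are not independent replicates, so these tests describe the 2 group values. Chromosome arms were compared by Fisher's exact test, two-sided. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

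The list test was tested on simulated data made from the 7058 tested genes. In 10 planted lists of 20 genes, 10 genes per list were set as called lower. All 10 lists were recovered, which the planting makes near certain, so this checked the computation and not the power of the test. With values shuffled among genes of similar abundance, 3 of 52 Fisher tests still passed the threshold, against 0 of 52 with random lists matched on abundance. The shuffle and these random lists used the same 20 classes of abundance, so a low count for the random lists was built in. Calls were more frequent among abundant genes, and Fisher's test does not take this into account, so results with random lists matched on abundance alone, and on abundance and length together, are given beside the lists that passed it. The p-value with random lists is one-sided, unlike that of Fisher's test. It is the share of random lists with at least as many called members, adjusted over the 52 tests.

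The named genes were fixed by a rule. It took Kr-h1, the 10 called genes with the largest ratio in each direction, the 3 highest called genes listed at 0 in the other group in each direction, up to 4 called members per list with the largest ratio (or up to 2 uncalled members with the highest mean FPKM), 10 genes tied to insulin signalling, fat metabolism and moulting, and the 3 most abundant genes per group. Alternatives changed the q threshold, the fold requirement, filters on low FPKM, the pseudocount, the scaling, the treatment of loci with several symbols and the background of the list test. Further alternatives, chosen after the data had been seen, matched random lists on exonic length, corrected ratios for length, left out loci shared between rows and left out genes listed at 0.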

Results

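Transcript levels were compared between whole larvae labelled wildtype and larvae labelled kr-h1 mutant, at 100 h after egg laying. Kr-h1 (Krüppel homolog 1) is a zinc-finger transcription factor induced by juvenile hormone. Each group was represented by 2 libraries, which the authors combined into 1 FPKM value per gene, so values below carry no replicate error. The depth of the libraries is unknown. Summed over all loci, the values came to 566151 FPKM in the wildtype-labelled and 543224 FPKM in the mutant-labelled group. The highest listed values in both groups were those of the larval cuticle protein genes Lcp4 (20804 FPKM in wildtype-labelled and 19773 FPKM in mutant-labelled larvae) and Lcp3 (10964 and 9133 FPKM), and of Obp99b, an odorant-binding protein family gene (8453 and 8906 FPKM). How Cuffdiff valued the 5 loci set aside for too many fragments was not examined. This ranking, the FPKM totals and the shares of them may therefore miss abundant transcripts. The 20 most abundant genes held 20.3% of the wildtype-labelled total and 19.2% of the mutant-labelled total.

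Kr-h1 itself was 3.28-fold higher in the libraries labelled kr-h1 mutant. Its level was 2.98 FPKM in the wildtype-labelled group and 9.79 FPKM in the mutant-labelled group, with a Cuffdiff q-value of 0.000889 in the authors' deposited table. The gene was listed at positions 6082603 to 6096498 of chromosome arm 2L, and no other row of the table overlapped it. The level of the mutated gene was therefore not lower under the mutant label. The label alone does not fix this level, since a mutant allele can still be transcribed. The direction of every difference below rests on the group labels, and the groups are called wildtype-labelled and mutant-labelled throughout.

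The comparison asked which transcripts differ in level when Kr-h1 is mutated. Among 7058 tested genes, 921 (13.0%) were called different in the authors' deposited table, with 305 higher and 616 lower in mutant-labelled larvae. Among the 887 called genes with values above 0 in both groups, the median fold was 1.48. With an absolute log2 ratio of at least 1 required, the balance turned to 99 higher and 74 lower genes (42.8% lower, against 66.9% of all called genes). The share of genes called rose with abundance, from 4.44% below 10 FPKM to 49.3% at 100 FPKM or more.

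The largest decreases included nol, which was 15.7-fold lower in mutant-labelled larvae (249 to 15.8 FPKM), CG13560 (266 to 19.96 FPKM, 13.3-fold) and CG7299 (1393 to 185 FPKM, 7.51-fold). CG17105 was listed at 377 FPKM in wildtype-labelled larvae and at 0 in mutant-labelled larvae. It lies on arm 2L at 10681030 to 10681775, near CG7299 at 10683427 to 10684409. The row of the metallothionein gene MtnC, which also covers a non-coding RNA, went from 21.1 FPKM to a listed 0, and CG41378 from 10.45 FPKM to 0. Lower genes listed at 0 in mutant-labelled larvae also included Brd, a Bearded family gene of the Notch pathway (6.45 FPKM in wildtype-labelled larvae), CG31609 (7.78 FPKM), CG8087 (7.31 FPKM) and CG13228 (5.21 FPKM). Each of these genes was called in the authors' deposited table, where the row of nol shares its locus with another row.

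The largest increases included Amyrel, an amylase-related gene, which was 27.6-fold higher in mutant-labelled larvae (1.44 to 39.7 FPKM) in a row that shares its locus with another. CG1304 was 18.6-fold higher (2.35 to 43.6 FPKM). The snRNA gene snRNA:U2:34ABa was listed at 0 in wildtype-labelled and at 160 FPKM in mutant-labelled larvae, the Bomanin immune peptide gene BomS3 at 0 and 45.2 FPKM, and CG42832 at 0 and 25.5 FPKM. The snRNA gene has 192 nucleotides and CG42832 has 252. FPKM is scaled to transcript length, so few fragments can give a high value for genes this short. How well the libraries of polyadenylated RNA captured the snRNA is unknown. Dim1 (16.5 FPKM), CARPB (15.1 FPKM), CG14245 (9.34 FPKM), whe (7.13 FPKM) and tut (6.77 FPKM) were likewise listed at 0 in wildtype-labelled larvae, with CG14245 in a row that shares its locus. Among all called genes, 25 were listed at 0 in wildtype-labelled and 9 in mutant-labelled larvae. These 34 genes had a median exonic length of 739.5 nucleotides.

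**Figure D1:**
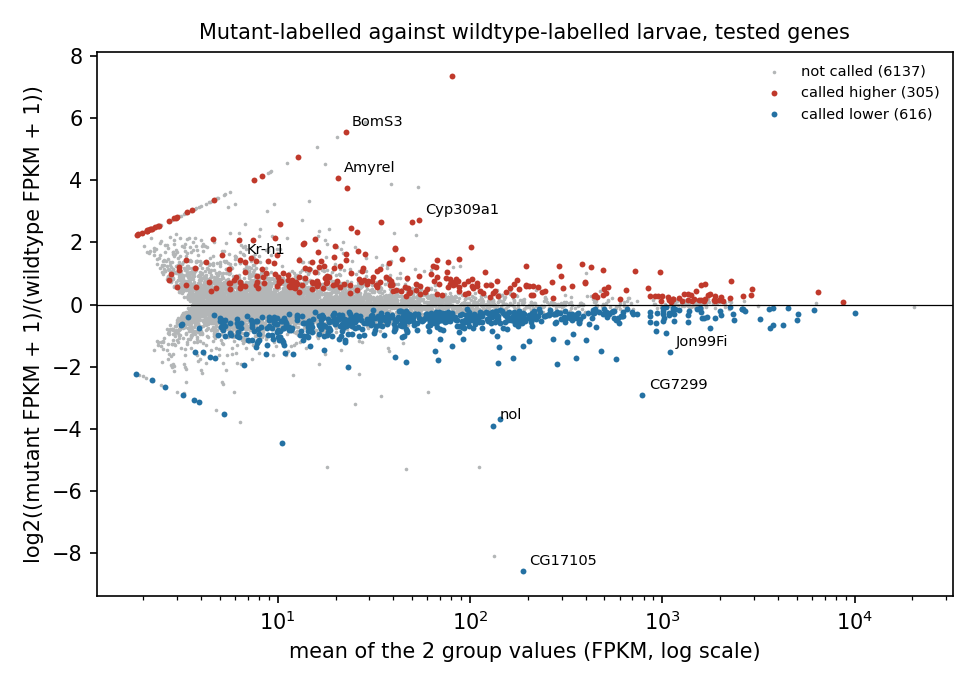
Each point is 1 of the tested genes, with the mean of the 2 group FPKM values on the horizontal log axis and log2((mutant-labelled FPKM + 1)/(wildtype-labelled FPKM + 1)) on the vertical axis. Red points are the 305 genes called higher and blue points the 616 called lower in the authors' deposited table, and Kr-h1 lies above 0.

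Genes of carbohydrate metabolism were lower in mutant-labelled larvae. Of 29 tested members, 17 fell, 0 rose and 12 were not called, and the count adjusted over the list alone was 19 lower. The glucose transporter gene Glut1 was 2.35-fold lower (8.86 to 3.77 FPKM), the hexokinase gene Hex-A 1.70-fold lower (18.1 to 10.6 FPKM), the fructose-1,6-bisphosphatase gene fbp 1.69-fold lower (117 to 69.3 FPKM) and the pyruvate carboxylase gene PCB 1.62-fold lower (123 to 75.9 FPKM). The list held more lower genes than the other tested genes (Fisher's exact test, two-sided, adjusted p = 3.99e-10), and its median log2 ratio was -0.36. With random lists the adjusted p, one-sided, was 0.00347 when matched on abundance and 0.0139 when matched on abundance and exonic length. In the same whole-larva libraries 13 of 18 muscle markers and 7 of 11 larval serum and fat body proteins were called lower. In these lists 0 and 2 were called higher. Random lists matched to them on abundance and length held a mean of 8.50 and 5.16 lower genes. The shares of muscle markers and of serum and fat body proteins in the FPKM total went from 3.41% to 2.94% and from 6.49% to 5.57%. Glut1 and PCB share their loci with other rows.

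Genes of lipolysis and fatty acid oxidation were also lower, with 12 of 26 tested members called lower, 1 higher and 13 not called (adjusted over the list alone, 16 lower and 3 higher). The triglyceride lipase gene bmm (brummer) fell 1.53-fold, from 22.3 to 14.6 FPKM, with a Cuffdiff q-value of 0.0154 in the authors' deposited table. The row of the lipase gene Lip4, which also covers CG18301, fell 2.73-fold (21.4 to 7.85 FPKM). Mtpbeta, a subunit of the mitochondrial trifunctional protein of fatty acid oxidation, fell 1.87-fold (114 to 61.1 FPKM), and the medium-chain acyl-CoA dehydrogenase gene Mcad fell 1.604-fold (219 to 137 FPKM). CG17544 was the member called higher (5.62 to 11.2 FPKM). Hsl, the hormone-sensitive lipase gene, had 4.49 and 3.04 FPKM and was not called (q-value 0.295 in the authors' deposited Cuffdiff table). The excess of lower genes passed Fisher's exact test, two-sided (adjusted p = 5.62e-06; median log2 ratio -0.37), and random lists gave an adjusted p of 0.00607 when matched on abundance and 0.0218 when matched on abundance and length. These genes were lower beside 13 of 18 muscle markers and 7 of 11 serum and fat body proteins. For these marker lists, random lists matched on abundance and length held a mean of 8.50 and 5.16 lower genes. Mtpbeta, Mcad and CG17544 share their loci with other rows.

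In fatty acid and triacylglycerol synthesis, 9 of 23 tested genes fell and 1 rose, and these counts were identical when adjusted over the list alone. The acetyl-CoA synthase gene AcCoAS fell 1.42-fold (191 to 135 FPKM), the mitochondrial glycerol-3-phosphate oxidase gene Gpo1 1.43-fold (111 to 77.9 FPKM) and SREBP, a transcription factor of lipid synthesis, 1.36-fold (35.0 to 25.8 FPKM). The fatty acid synthase gene FASN3 rose 1.78-fold (7.33 to 13.0 FPKM). The list passed Fisher's exact test, two-sided (adjusted p = 0.000428). In permutation with random lists the adjusted p was 0.0498 when matched on abundance and 0.602, no longer past the threshold, when matched on abundance and length. These genes too were lower beside 13 of 18 muscle markers and 7 of 11 serum and fat body proteins, where such random lists held a mean of 8.50 and 5.16. SREBP shares its locus with another row.

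**Figure D2:**
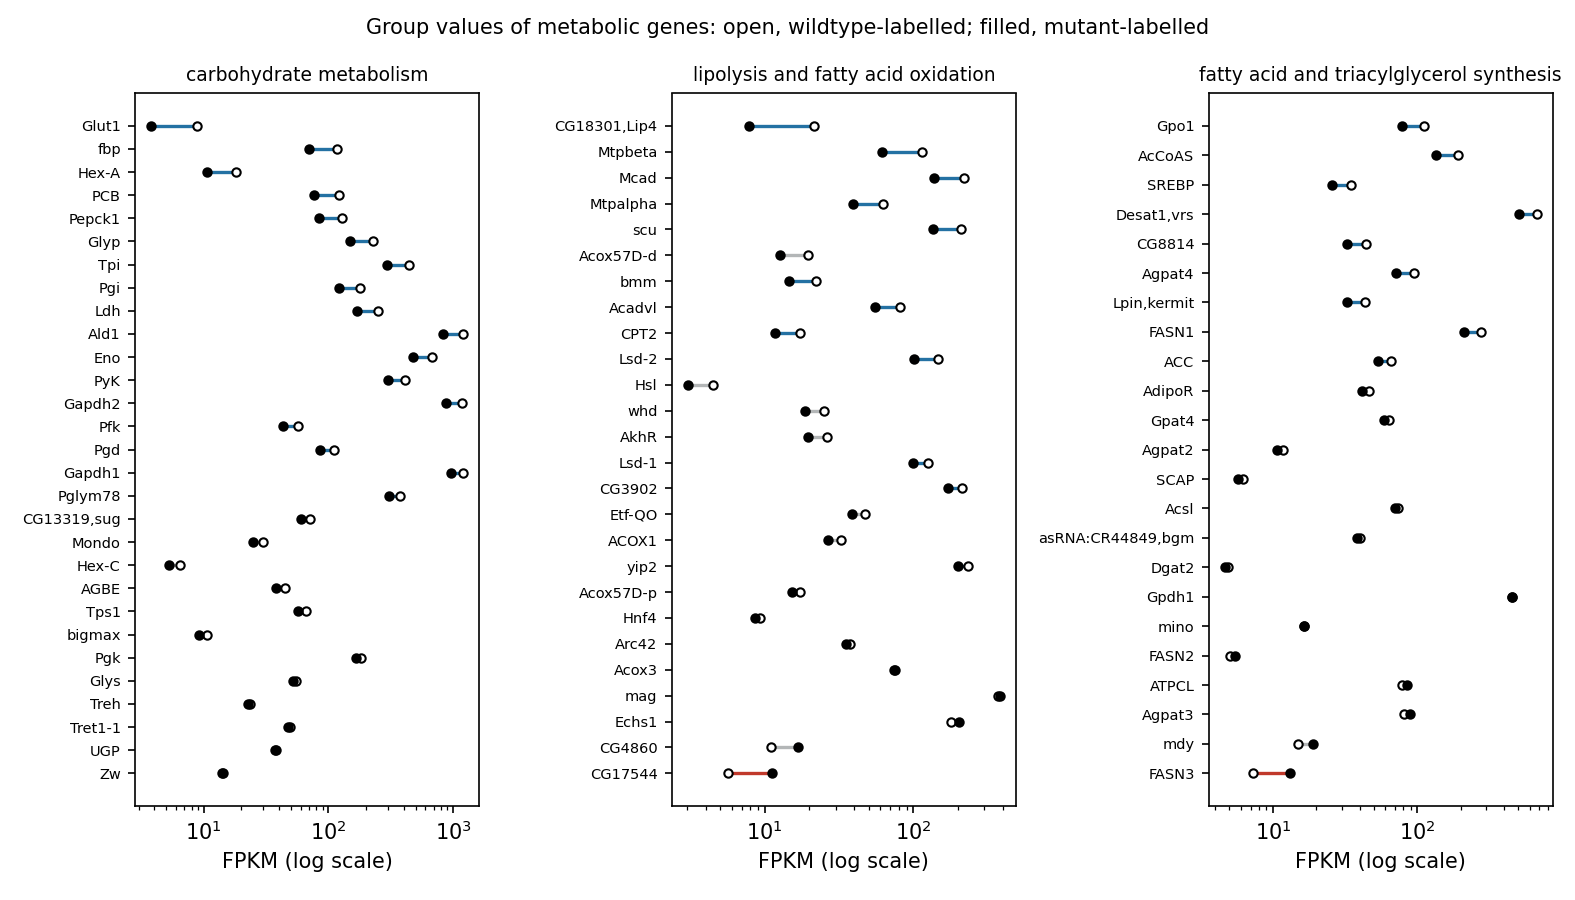
Every tested member of the carbohydrate metabolism, lipolysis and fatty acid oxidation, and fatty acid and triacylglycerol synthesis lists is shown as an open point (wildtype-labelled FPKM) and a filled point (mutant-labelled FPKM) on a horizontal log axis. Blue lines mark genes called lower, red lines genes called higher and grey lines genes not called, and 17 of 29, 12 of 26 and 9 of 23 genes were called lower.

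Genes of insulin, TOR and FOXO signalling were not called in either direction. The deposited Cuffdiff table called 0 of 25 tested members, with 0 when adjusted over the list alone and 2 at an unadjusted p under 0.05. Thor, the 4E-BP gene and a target of FOXO, had 67.1 FPKM in wildtype-labelled and 73.4 FPKM in mutant-labelled larvae. The values of foxo were 6.57 and 8.08 FPKM, those of the insulin-like peptide gene Ilp6 8.58 and 12.9 FPKM, and those of Rheb 23.1 and 27.0 FPKM. The insulin receptor gene InR (1.69 and 1.16 FPKM) and the adipokinetic hormone gene Akh (3.46 FPKM and a listed 0) were not tested by the authors. The largest folds in the list, named after their values were seen, were those of the insulin-like peptide genes Ilp3 (5.35 and 0.442 FPKM) and Ilp2 (10.8 and 2.15 FPKM), which were not called (q-values 0.408 and 0.254 in the authors' deposited Cuffdiff table). Differences of this size among low genes thus went uncalled, and the count of 0 does not show that the list was unchanged. The list stood apart from the other genes in neither direction (Fisher's exact test, two-sided, adjusted p = 0.906 for higher and 0.423 for lower). InR, Ilp2, Ilp3 and Ilp6 share their loci with other rows.

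Muscle genes were lower in mutant-labelled larvae, with 13 of 18 tested members called lower and 0 higher (16 lower when adjusted over the list alone). The myosin heavy chain gene Mhc fell 1.53-fold (500.4 to 326 FPKM), the giant sarcomere protein gene sls 1.47-fold (23.9 to 16.2 FPKM), the paramyosin gene Prm 1.44-fold (276 to 192 FPKM) and the muscle LIM protein gene Mlp84B 1.41-fold (207 to 146 FPKM). Together the muscle genes made up 3.41% of the wildtype-labelled and 2.94% of the mutant-labelled FPKM total. The excess passed Fisher's exact test, two-sided (adjusted p = 1.49e-09) and random lists matched on abundance (adjusted p = 0.0039), and was not past the threshold with random lists matched on abundance and length (adjusted p = 0.159). The loci of sls and Mlp84B are shared with other rows.

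Genes on the list of larval serum and fat body proteins fell in 7 of 11 tested genes and rose in 2, with identical counts adjusted over the list alone. Fbp2, in a row with CG42847, was 1.68-fold lower (4571 to 2716 FPKM), the row of the cuticle protein gene Lcp9 and egg 1.58-fold lower (4597 to 2912 FPKM), Fbp1 1.45-fold lower (201 to 139 FPKM) and the larval serum protein gene Lsp2 1.38-fold lower (3733 to 2706 FPKM). The row of Lcp9 and egg was also counted as lower in the cuticle list. Haemocyte markers fell in 4 of 10 tested genes (5 adjusted over the list alone), among them the scavenger receptor genes Sr-CI (8.57 to 3.72 FPKM, 2.31-fold) and crq (26.2 to 15.8 FPKM, 1.66-fold). In chitin metabolism 9 of 31 genes fell and 3 rose (10 and 3 adjusted over the list alone), with obst-E 1.38-fold lower (433 to 315 FPKM), Cht9 1.43-fold lower (123 to 86.0 FPKM) and obst-I listed at 0 and 5.80 FPKM. Fisher's exact test, two-sided, gave adjusted p = 7.81e-05 for serum and fat body proteins, 0.0325 for haemocyte markers and 0.00503 for chitin metabolism, all for lower genes. With random lists these became 0.194, 0.145 and 0.277 when matched on abundance, and 0.633, 0.632 and 0.712 when matched on abundance and length. The rows of Fbp2, Lcp9, Lsp2, crq, Cht9 and obst-I share their loci with other rows.

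Cytoplasmic ribosomal protein genes were higher in mutant-labelled larvae, with 27 of 89 tested members called higher and 5 lower (31 and 10 adjusted over the list alone). RpL39 rose 1.35-fold (1269 to 1715 FPKM), RpL41 1.32-fold (5587 to 7357 FPKM), RpL37A 1.27-fold (1572 to 1991 FPKM) and RpS16 1.26-fold (1151 to 1448 FPKM), all in rows that share their loci with others. Ribosomal protein genes made up 21.3% of the wildtype-labelled and 23.6% of the mutant-labelled FPKM total. In the same libraries the share of muscle markers went from 3.41% to 2.94% and that of serum and fat body proteins from 6.49% to 5.57%. The excess of higher genes passed Fisher's exact test, two-sided (adjusted p = 1.04e-14), and random lists matched on abundance (adjusted p = 0.00347) and on abundance and length (adjusted p = 0.0139). The median log2 ratio of the list was 0.06, which became 0.02 after correction for length and 0.10 when centred on the median of all genes.

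Heat shock genes rose as well, in 6 of 16 tested members, while 2 fell (7 and 2 adjusted over the list alone). The row of the small heat shock gene Hsp22, which also covers CG4456, rose 5.49-fold (7.94 to 43.6 FPKM), Hsp26 3.25-fold (10.6 to 34.6 FPKM), Hsp68 2.84-fold (8.70 to 24.7 FPKM) and the co-chaperone gene DnaJ-1 1.68-fold (13.2 to 22.2 FPKM). The list passed Fisher's exact test, two-sided, for higher genes (adjusted p = 0.000255; median log2 ratio 0.44), and random lists matched on abundance (adjusted p = 0.00347) and on abundance and length (adjusted p = 0.0052). Hsp68 shares its locus with another row.

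Digestive enzyme genes went both ways, with 13 of 44 tested members higher and 13 lower (17 and 15 adjusted over the list alone). The maltase genes Mal-A3 (17.8 to 63.3 FPKM, 3.56-fold) and Mal-A8 (23.1 to 65.2 FPKM, 2.82-fold) and the amylase gene Amy-d (3.35 to 10.2 FPKM, 3.06-fold) rose, whereas the serine protease gene Jon99Fi fell 2.91-fold (1630 to 559 FPKM). Cuticle protein genes rose in 7 and fell in 8 of 54 tested members (7 and 10 adjusted over the list alone), with Lcp65Ag3 2.38-fold higher (115.3 to 274 FPKM) and Cpr67Fa2 3.39-fold lower (882 to 260.2 FPKM). Nuclear-encoded respiratory chain genes fell in 14 and rose in 4 of 75 (16 and 5 adjusted over the list alone). Among these, the row of ND-13B and CG33493 was 1.79-fold lower (168 to 93.7 FPKM) and UQCR-11 was 3.67-fold higher (43.4 to 159 FPKM). Fisher's exact test, two-sided, gave adjusted p = 2.86e-07 for higher and 0.000399 for lower digestive genes, 0.0325 for higher cuticle genes and 0.0277 for lower respiratory chain genes. With random lists matched on abundance the adjusted p was 0.0052 for higher and 0.839 for lower digestive genes, 0.577 for cuticle genes and 1 for respiratory chain genes. With matching on abundance and length it was 0.0218, 0.0615, 0.717 and 1. Many digestive and cuticle genes have near-identical copies, so their single values are uncertain, and the rows of Mal-A8 and ND-13B share their loci with other rows.

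**Figure D3:**
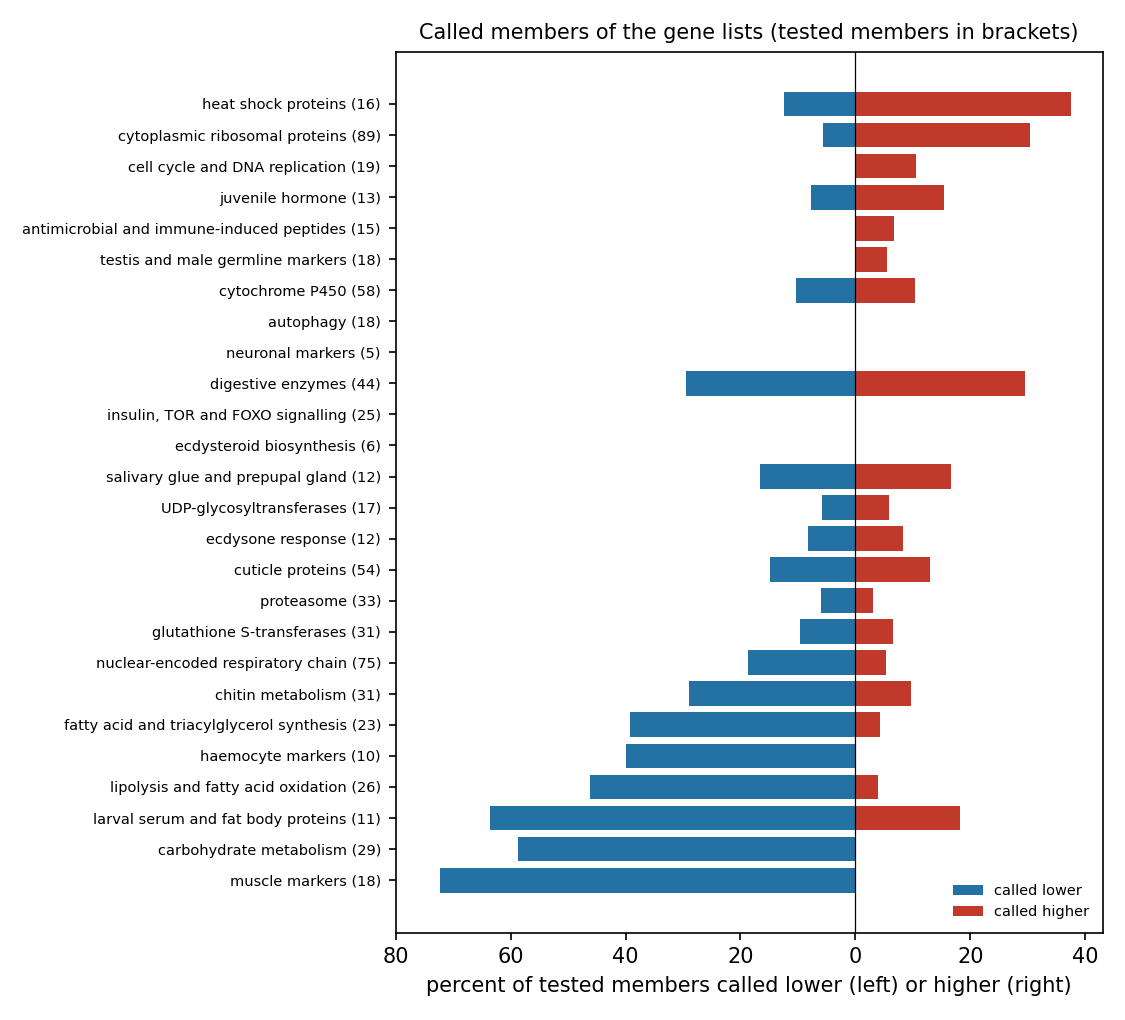
For each gene list, bars show the percent of tested members called lower (blue, to the left of 0) and higher (red, to the right of 0) in the authors' deposited table, with the number of tested members in brackets. Muscle markers (13 of 18) and carbohydrate metabolism (17 of 29) reach far to the left, ribosomal protein genes (27 of 89) and heat shock genes (6 of 16) to the right, and the insulin list has no bar.

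Each hormone response list held at most 13 tested genes, and 13.0% of all tested genes were called. Among juvenile hormone genes 2 of 13 rose and 1 fell (identical when adjusted over the list alone), with Jheh3, a juvenile hormone epoxide hydrolase gene, 1.26-fold higher (59.2 to 74.9 FPKM), Hsp83, also counted among the heat shock genes, 1.25-fold higher (149 to 185 FPKM) and Nup358 1.25-fold lower (12.7 to 10.1 FPKM). Among ecdysone response genes 1 of 12 rose and 1 fell (identical when adjusted over the list alone). These were Cth (65.0 to 103 FPKM, 1.58-fold higher) and the shared row of Actn and the ecdysone receptor partner gene usp (126 to 93.7 FPKM, 1.34-fold lower). The broad gene br had 13.7 and 10.9 FPKM and was not called, and Eip93F (0 and 0.222 FPKM) was not tested. In ecdysteroid biosynthesis Cuffdiff called 0 of 6 genes, also when adjusted over the list alone, with 2 at an unadjusted p under 0.05. None of these 3 lists passed Fisher's exact test, two-sided, in either direction, with adjusted p of at least 0.325. Hsp83, br and the row of Actn and usp share their loci with other rows.

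The ratio moved with gene length. Among the 1409 shortest genes (140 to 1017 nucleotides) 101 genes were called higher and 79 lower, with a median log2 ratio of 0.11. Among the 1409 longest (3647 to 71820 nucleotides) 44 were higher and 160 lower, with a median of -0.09. Across 7044 genes, which are not independent replicates, Spearman's rho between length and ratio was -0.13, -0.26 among 1675 genes with a mean of at least 30 FPKM and -0.07 among 5676 genes of at least 1000 nucleotides. The median length was 944 nucleotides for tested ribosomal protein genes, 2486 for carbohydrate metabolism, 2326 for lipolysis and fatty acid oxidation, 3152 for lipid synthesis, 2726 for muscle, 2625 for serum and fat body proteins and 2182.5 for heat shock genes.

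**Figure D4:**
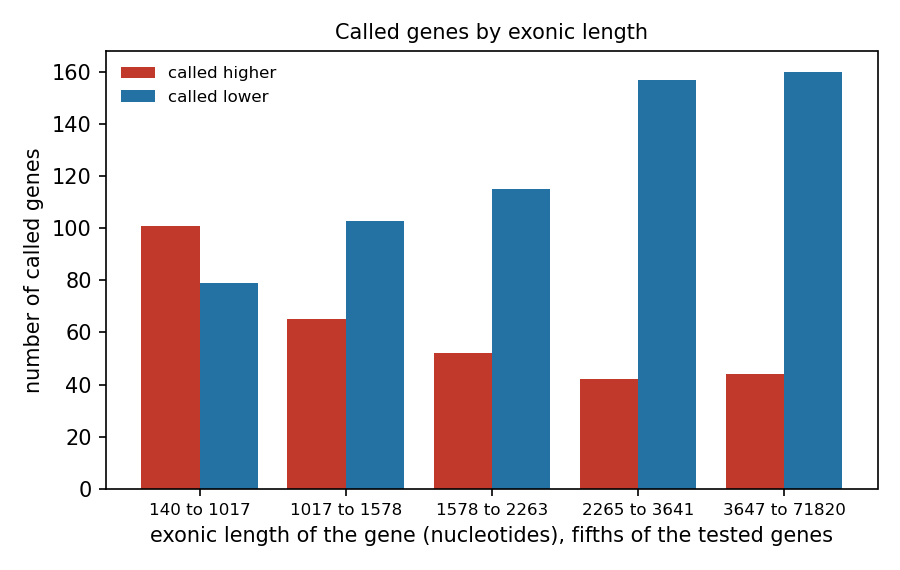
Bars give the number of genes called higher (red) and lower (blue) in mutant-labelled larvae in 5 classes of about equal size of the tested genes, ordered by exonic length in nucleotides. Higher genes go from 101 in the shortest to 44 in the longest class, and lower genes from 79 to 160.

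Because a homozygous allele brings its flanking chromosome with it, calls were compared along the chromosomes. Within 1 Mb of Kr-h1, 16.7% of 138 tested genes were called, against 12.1% on the rest of arm 2L (Fisher's exact test, two-sided, p = 0.135). Within 2 Mb the shares were 15.8% and 11.8% (Fisher's exact test, two-sided, p = 0.0921). Arm 3L had the highest share, 15.2% of 1389 genes, which did not pass the threshold over the 6 arms (Fisher's exact test, two-sided, p = 0.00989, adjusted p = 0.0593).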

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

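The matched random lists, the length correction and the removal of shared loci and of genes at 0 were chosen after the result was seen. No paired analysis was possible because the deposited columns carry no replicate, and leaving out each replicate could not be run for that reason. The number of higher genes was 170 at a q threshold of 0.01, 460 at 0.1, 99 with an absolute log2 ratio of at least 1 and 196 without shared loci. The number of lower genes was 400 at a q threshold of 0.01, 74 with that ratio and 387 without shared loci; the other settings kept both counts within 1.5 times. Fewer genes could be called in each of these except at 0.1. Of 9 lists with an excess of lower genes, 4 passed with random lists matched on abundance, 2 with matching on abundance and length, and 3 when such lists were drawn from genes outside the list; the cause was not tested beyond length. In that order of settings the adjusted p was 0.0039, 0.159 and 0.098 for muscle and 0.839, 0.0615 and 0.0182 for lower digestive genes. By Fisher's exact test, 7 lists of lower genes passed without loci of several symbols (adjusted p = 0.0604 for respiratory chain and 0.0701 for haemocyte genes), 7 without shared loci (0.157 for chitin and 0.878 for haemocyte genes) and 8 at a q threshold of 0.01 (0.852 for haemocyte genes), and higher cuticle genes did not pass without shared loci (0.335). The higher lists numbered 3 or 4 in every setting. Arm 3L passed at a q threshold of 0.01, with 10.2% of genes called (Fisher's exact test, adjusted p = 0.0123), and the cause was not tested. The median log2 ratio of respiratory chain genes turned from -0.02 to 0.015 when centred on the median of all genes, whose shift was -0.03. That of cell cycle and DNA replication genes turned from -0.02 to 0.014. Correction for length moved 8 of 26 list medians by more than the spread of random medians, and a pseudocount of 5 moved 2 (heat shock from 0.44 to 0.30, testis from 0.57 to 0.29). The ratio of Kr-h1 ran from 1.44 to 1.71, and each called named gene kept its direction with a pseudocount of 0.1 and when centred. A pseudocount cannot turn the sign of a ratio, so that setting tested no direction. The centring shift of -0.03 was small beside the ratios of these genes, so it tested little. The filter at a mean of 1 FPKM removed none of the tested genes, whose lowest mean was 1.83 FPKM, so it tested nothing. Unknown depth limits what can be said of low genes: 4.44% of those under 10 FPKM were called.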

Other observations

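The tests on Kr-h1, on the share of muscle and fat body and on neighbouring genes were chosen after the result was seen; the trend with length had also been seen before the length-matched lists and the lengths of genes at 0 were computed.

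Detoxification genes went both ways. Of 58 tested cytochrome P450 genes 6 rose and 6 fell (7 and 8 adjusted over the list alone), with Cyp309a1 6.90-fold higher (13.7 to 94.5 FPKM) and Cyp28d2 3.75-fold lower (73.2 to 19.5 FPKM) in mutant-labelled larvae. Among 31 glutathione S-transferase genes 2 rose and 3 fell (4 and 3 adjusted over the list alone), including GstE5 (20.9 to 47.5 FPKM), and among 17 UDP-glycosyltransferase genes 1 rose and 1 fell (3 and 2 adjusted over the list alone), Ugt37B1 (7.15 to 25.4 FPKM) and Ugt37A3 (41.9 to 21.8 FPKM). The stress-induced gene TotA was 3.76-fold lower (449 to 119 FPKM). Salivary glue and prepupal gland genes rose in 2 and fell in 2 of 12 (2 and 3 adjusted over the list alone), with ng1 2.64-fold higher (42.5 to 112 FPKM) and Sgs8 1.31-fold lower (699 to 535 FPKM). No list in this paragraph passed Fisher's exact test, two-sided, and the Turandot list of TotA was too small for it. The locus of ng1 is shared with another row.

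Testis and male germline markers had a median log2 ratio of 0.57, at the 99.99 percentile of abundance-matched and the 98.52 percentile of abundance- and length-matched random lists. The median was 0.29 with a pseudocount of 5. Of the list 1 of 18 was called higher, Mst98Ca (8.13 to 19.5 FPKM), and 0 when adjusted over the list alone. The male-specific RNA gene roX1 had 25.7 and 29.1 FPKM and was not called. Antimicrobial and immune-induced peptides had a median of 0.40 (percentiles 99.92 and 99.18), with 1 of 15 called, BomS3, also when adjusted over the list alone. Proteasome genes rose in 1 and fell in 2 of 33 (0 and 2 adjusted over the list alone), with Rpn1 1.38-fold lower (33.9 to 24.5 FPKM). Cell cycle genes rose in 2 of 19, PCNA (20.4 to 34.1 FPKM) and polo (8.96 to 14.8 FPKM), also when adjusted over the list alone. Cuffdiff called 0 of 18 autophagy genes and 0 of 5 neuronal markers, each with 1 at an unadjusted p under 0.05, and 0 of 3 tested clock genes, with 1 at an unadjusted p under 0.05 and Pdp1 at 6.23 and 9.41 FPKM. Of Osiris genes 0 were tested, and the row of the eye colour gene w, which covers CG32795 too, rose from 46.0 to 128 FPKM. The loci of roX1 and w are shared with other rows.

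Kr-h1 was 3.28-fold higher in the libraries labelled mutant. The length trend is argued against, since the median log2 ratio of genes of similar length was -0.065, against 1.44 for Kr-h1. Reads of a neighbouring gene stay open: of 18 tested genes within 50 kb the upper quartile was 0.225, but the highest, CG31642, had 1.62 (0.883 to 4.80 FPKM, not called), while CG9175, between it and Kr-h1, had 0.24. CG31642 shares its locus with stai (13.7 to 9.66 FPKM, not called), so its value is uncertain. An exchange of the group labels could turn every direction given here. It cannot be told apart from a mutant allele that is transcribed at a higher level. The labels fix the level of no gene, and the table has no value per library. Higher transcription of the mutant allele, a biological difference that the design names, was not tested.

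The gene groups may follow the trend with length. The medians of 4 of them lay outside the central 95% range of random lists matched on abundance and length. These were carbohydrate metabolism at the 0.05 percentile, lipolysis and fatty acid oxidation at 0.07, ribosomal proteins at 99.53 and heat shock at 100. The percentiles argue against the trend as the whole explanation of carbohydrate metabolism, of lipolysis and fatty acid oxidation, or of heat shock. Among shorter tested genes, the 8 of carbohydrate metabolism had a median of -0.31 and the 9 of lipolysis and fatty acid oxidation -0.21. All shorter genes had 0.02. The 11 longer heat shock genes had 0.27, against -0.08 for all longer genes. This split was not matched on abundance, and matching of every list used only 10 classes of abundance and of length. How much of the carbohydrate and lipolysis medians the trend makes is therefore open. For ribosomal protein genes the trend stays open as the whole explanation. These genes were short and abundant, and the trend was steeper among abundant genes (rho -0.26 at 30 FPKM or more). The medians of muscle (15.85), lipid synthesis (61.22) and serum and fat body proteins (7.32) lay inside the range. The trend stays open as their explanation, although 3 of 4 shorter muscle genes were also called lower. Subtracting the median of genes of similar length moved the median log2 ratio from -0.36 to -0.28 for carbohydrate metabolism, -0.37 to -0.32 for lipolysis and fatty acid oxidation, 0.06 to 0.02 for ribosomal proteins, 0.44 to 0.44 for heat shock, -0.24 to -0.19 for muscle, -0.11 to -0.04 for lipid synthesis and -0.29 to -0.19 for serum and fat body proteins. What makes the trend is open, since RNA quality and fragment lengths per library were not analysed here. A lower share of muscle or fat body tissue stays open for all 3 metabolic lists. The marker medians (-0.24 for muscle and -0.29 for serum and fat body proteins) lay below that of lipid synthesis. They lay above those of the other lists by less than the spread of the markers. The serum and fat body list was not uniform as a marker of tissue. Its 7 lower rows of 11 included that of Lcp9 and egg, and 2 were called higher, among them Obp99b (8453 to 8906 FPKM). A difference between the genotypes was not tested as an explanation.

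Genes called while listed at 0 in one group may reflect short transcripts rather than absent ones. Their median length, 739.5 nucleotides, was below that of every one of 10000 abundance-matched sets (percentile 0, with a median of 1651.5 over the sets), and 29 of 34 had a mean under 10 FPKM. Single genes differ from this. CARPB, listed at 0 and 15.1 FPKM, has 8793 nucleotides, and CG17105, of 746 nucleotides, went from 377 FPKM to a listed 0. No biological explanation was tested.

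Among 173 genes called with an absolute log2 ratio of at least 1, 5 pairs of adjacent tested genes changed the same way, against a mean of 1.77 in 10000 permutations within arms (permutation p = 0.0319, one-sided). The upper end of the central 95% of permutations was also 5, so the count did not exceed the bound set for it. The pairs, named after their values were seen, were CG13560 with CG11300 and CG11590 with Prp16, which were lower, and CG13311 with CG34426, Hsp22 with Hsp26 and Ser6 with CG1304, which were higher. Prp16 shares its locus with another row. CG17105 and CG7299, both lower and near each other, were not among the pairs counted, so the count does not cover every case of nearby genes.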
